A study of Mus musculus with 19 samples.

How the data were processed

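Footprints, RNA and translated ORFs were analysed in mouse organoids of strain C57BL/6, in 19 samples. Per the labels, organoids were plated for 48 hours and treated with 100 µM cycloheximide, which arrests elongating ribosomes, for 5 minutes before harvest. The labels give the RNA libraries the footprint extraction protocol too, so how the RNA libraries were made is not given in the sources used here. Groups were taken from the labels, and the ORF libraries titled KP are the LUAD group by their source label.

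Footprint and RNA tables hold estimated counts per transcript, made by the authors with kallisto per the submitters' processing notes, whose version, transcript release and genome build are not given in the sources used here. The deposited TPM values, which kallisto computes from the estimated counts and effective lengths, were used in an alternative only. The ORF lists give, per the file headers, counts of footprint P-sites (the position of the ribosome's peptidyl site) by reading frame, a deposited RPKM value per ORF and the authors' p-value for an excess of in-frame P-sites, on genome build mm10 per the submitters' processing notes. The ORF caller is not given in the sources used here, and no listed p-value exceeds 0.05.

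No table pairs all transcripts with genes, so transcripts were paired with genes through the ORF lists. These pair 22871 transcripts with gene names, 22509 of which (98.4%) are in the count tables of 118489 transcripts, and they cover 7266 genes, 7264 of whose IDs are in the name table. Of these genes 4113 come from LUAD lists alone, 554 from AT2 lists alone and 2599 from both, so the gene tables favour genes translated in LUAD. From 65.0% to 70.0% of a library's counts were paired. Estimated counts were summed to genes and rounded to whole numbers. Gene coordinates come from GRCm38.p6, which is mm10, matched on the symbol. Genes that share reads with near-identical copies, such as H2-K1, H2-Q4, Rps4l and the histone genes, are uncertain.

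Each assay was fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and footprints per RNA as the interaction of tissue and assay over 14 libraries. CPM values use the TMM-scaled library size. Lists of genes (AT2 identity, AT1, transitional alveolar, gastric and gut endoderm, EMT, oncofetal, p53 targets, RAS-MAPK output, cell cycle, ribosome biogenesis, translation factors, integrated stress response, unfolded protein response, MHC class I and II, interferon, NF-kB, cholesterol, fatty acid and surfactant lipid, glycolysis and hypoxia, NRF2, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, mitochondrially encoded, proteasome, histones, nuclear noncoding RNA and markers of club, ciliated, basal, fibroblast, macrophage, endothelial and neuroendocrine cells) were tested with camera from limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were measured. Of these, MHC class II, ciliated, endothelial and nuclear noncoding RNA lists had 0 measured members. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 8 protein-coding genes with the largest change in each direction past the test, with a mean of at least 50 counts per library in the higher group (20 footprint and 20 RNA counts for footprints per RNA) and no overlap between groups, leaving out predicted genes. It adds up to 2 members per direction of each list and Trp53, Sftpc, Nkx2-1, Hmga2, Cdkn1a, Mki67, Ager, Hnf4a, Atf4, H2-K1, B2m and Cd74, and for ORFs the 10 with the highest P-site support. Only part of the genes it takes are described, and some are not reported here.

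AT2 and LUAD RNA libraries of the same number deviated together from their group means (correlation from 0.23 to 0.33 over 3 pairs), so the RNA numbers pair by that check, which rests on the data and not on the labels. Over all 6 pairs within a library set the range was the same, so numbers and sets are not told apart. No 2 replicates agreed within sampling noise (the lowest mean chi-square over genes was 5.42).

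On simulated counts with 200 changed genes, the footprint test (6733 genes) recovered 7% of 2-fold and 66% of 4-fold changes, the RNA test (6902 genes) 21% and 74%, and the test of footprints per RNA (7039 genes) 4% and 51%, with 5, 5 and 2 unchanged genes called. The changed genes were taken among those with a mean of at least 50 counts. Genes were drawn independently, without the library sets of the real data. These rates thus hold for well-covered genes and do not measure false calls under shared library effects. Depth per sample is given at the start of the report. ORF numbers and shares were compared with exact two-sided permutation tests, and shares of one library carry exact binomial intervals. ORFs were matched by the authors' ORF identifier, which holds the gene ID, genomic start, genomic stop and length. The plan had named chromosome, strand and coordinates. ORFs with the same ends but another length or gene ID therefore count as different. Alternatives included DESeq2 1.42.0 and its size factors, other filters, length-scaled counts, protein-coding transcripts, replicate blocks, limma voom, leaving out each library and stricter ORF thresholds. Added after seeing the data were library sets, scaling on all transcripts, a length trend, the gene Mettl26 left out, a minimum of 20 counts in every library for footprints per RNA, and ORFs that share a coding stretch left out. Python 3.11.15 with scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 served for the rest.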

Results

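Ribosome footprints and RNA were measured in mouse organoids of 2 kinds. One kind was grown from alveolar type 2 (AT2) cells, the surfactant-producing progenitors of the lung alveolus, and the other from lung adenocarcinoma (LUAD). Footprints were collected with RiboLace, a method that pulls down ribosomes engaged in translation and keeps the RNA fragment each one protects. The footprint part held 3 AT2 and 4 LUAD libraries, the RNA part 3 AT2 and 4 LUAD libraries, and a further part listed translated open reading frames (ORFs) in 2 AT2 and 3 LUAD libraries. The AT2 footprint libraries held 3.03, 3.49 and 3.83 M estimated counts, and the LUAD footprint libraries 4.80, 14.17, 13.34 and 14.25 M. RNA depth was 9.57, 10.23 and 4.12 M estimated counts in AT2 and 32.92, 33.20, 29.29 and 27.18 M in LUAD. Nothing in the labels says that the footprint or RNA libraries of one kind came from separate cultures, so their p-values measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only.

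The first comparison asked which genes were translated at other levels in LUAD than in AT2 organoids. Footprints of Trp53, the gene of the tumour suppressor p53 (mm10, chromosome 11, 69580348 to 69591873), stood at 55.99, 80.94 and 52.51 CPM (counts scaled to one library size) in the AT2 libraries. In the LUAD libraries they stood at 1.21, 0, 0.609 and 0.513 CPM, a log2 fold change of -6.95 ± 0.77 (SE, n = 3 and 4; edgeR adjusted p = 0.000923). Its target Cdkn1a, an inhibitor of cell division, fell from 343 ± 33.2 to 26.5 ± 10.9 CPM (SD, n = 3 and 4). Nkx2-1, the transcription factor that sets lung identity (chromosome 12, 56531935 to 56536908), had 844 footprint counts over the AT2 libraries and 2 over the LUAD libraries, a ratio of 2457 with a 95% counting interval of 678 to 20318. Sftpb, which encodes surfactant protein B, averaged 25.6 ± 7.01 CPM in AT2 and had no footprint count in LUAD. It was at least 454-fold lower against a floor of 3 counts over the group. In the other direction, Lgals4, a lectin of the gut epithelium (chromosome 7, 28833122 to 28841710), had no AT2 footprint and was at least 48.8-fold higher in LUAD. Hnf4a, a transcription factor of gut and liver, rose from 1.41 ± 2.43 to 30.3 ± 7.47 CPM.

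Across genes, 1452 of 6820 passed the edgeR quasi-likelihood test at an adjusted p of 0.05, of which 668 were higher and 784 lower in LUAD. Scaling on all transcripts moved the median log2 fold change by 0.149 and gave 867 higher and 612 lower calls, so directions are given relative to the genes with a listed ORF. Among the genes with the largest changes, Obsl1, Zfp53, Tnnt2 and Hgfac had no AT2 footprint and were at least 39.3-, 42.5-, 31.9- and 25.4-fold higher in LUAD. Apob was at least 107-fold higher (adjusted p = 0.0257). Its adjusted p was 0.0653 without AT2 library 2, 0.0699 without AT2 library 3 and 0.0523 without LUAD library 2. Scnn1g, a subunit of the epithelial sodium channel, had 787 AT2 counts against 1 in LUAD (ratio 4581, interval 820 to 181178), and Ndnf fell from 924 ± 144 to 0.998 ± 1.31 CPM. Hmga2, a chromatin protein of embryonic tissue, rose from 11.9 ± 5.86 to 90.6 ± 7.52 CPM, and Igf2bp2, an RNA-binding protein of fetal tissue, from 2.95 ± 0.489 to 53.6 ± 4.76 CPM. B2m (log2 fold change 0.11 ± 0.19, adjusted p = 0.720) and Atf4 (0.53 ± 0.39, adjusted p = 0.385) did not pass. With the replicate numbers as a block 933 genes passed, and without LUAD library 2, 3 or 4 there were 904, 841 and 856. Libraries fell into 2 sets, which were drawn from these same libraries and are described at the end. Of the 1452 genes 1450 had the same sign in both. That was nearly fixed in advance, since 1443 of them had no overlap between AT2 and LUAD libraries. With the set as a term 2882 genes passed, 1451 of the 1452 among them. Because the sets were drawn from the spread of these libraries, such a term lowers the remaining spread, and the added calls are no independent support.

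**Figure D1:**
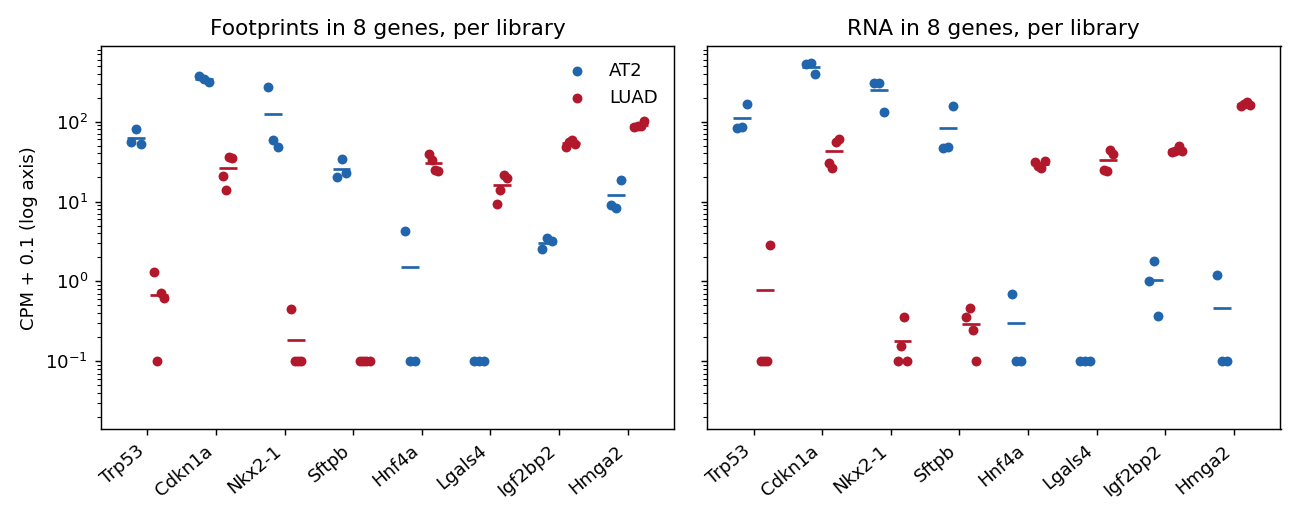
CPM plus 0.1 on a log axis for 8 genes in each footprint library (left) and RNA library (right), with AT2 libraries in blue, LUAD libraries in red and the group mean as a bar. Trp53, Cdkn1a, Nkx2-1 and Sftpb lie lower in LUAD and Hnf4a, Lgals4, Igf2bp2 and Hmga2 higher, in both assays.

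Gene lists fixed before the data were examined were set against all other genes with camera, and 14 of the lists with at least 5 measured members passed at the preset correlation. None of the 14 held with a correlation estimated from the libraries, and the p for each is given beside it. Cell cycle genes rose in 11 of 35 measured members and fell in 0 (adjusted p = 6.12e-06; adjusted p = 0.533 with an estimated correlation), among them Ccnb2 (log2 fold change 2.33) and Anln (1.97), and 15 rose when adjusted over the list alone. Mki67, a marker of cycling cells, rose from 133 ± 10.3 to 282 ± 18.0 CPM. Targets of p53 fell in 7 of 16 members and rose in 0 (adjusted p = 5.33e-05; adjusted p = 0.112 with an estimated correlation), with 8 adjusted over the list alone, and included Ddit4l (-5.54), Cdkn1a (-3.69) and Sesn2 (-3.66). AT2 identity genes fell in 5 of 9 members, and adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.000167; adjusted p = 0.226 with an estimated correlation). Genes of AT1 cells, the flat gas-exchange cells that AT2 cells give rise to, fell in 7 of 12 members and rose in 1 (adjusted p = 0.000653; adjusted p = 0.533 with an estimated correlation), or 7 and 2 adjusted over the list alone. Cldn18, a tight junction protein, fell by 8.90 on the log2 scale. Gastric and gut endoderm genes rose in 4 of 5 members, also 4 adjusted over the list alone (adjusted p = 0.00115, and 0.169 with an estimated correlation). Only these 5 of 25 defined members had a listed ORF. Of all paired genes, 4113 of 7266 entered through LUAD lists alone, so the filter favours members that rise and this list is weak support.

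NF-kB and inflammatory genes rose in 7 of 19 footprint members and fell in 2 (adjusted p = 0.00347; adjusted p = 0.304 with an estimated correlation; 8 and 2 adjusted over the list alone), with Il1a at 5.09 and Icam1, an adhesion molecule, at -3.26. Without AT2 footprint library 1 this list had an adjusted p of 0.0591. Transitional alveolar genes fell in 8 of 19 members and rose in 2 (adjusted p = 0.00347; adjusted p = 0.533 with an estimated correlation), or 10 and 4 adjusted over the list alone. Sfn (-3.24) and Tnip3 (-3.24) were among them, and the list had an adjusted p of 0.0604 without AT2 footprint library 2. Antigen presentation by MHC class I fell in 4 of 11 members, also 4 adjusted over the list alone (adjusted p = 0.0103; adjusted p = 0.226 with an estimated correlation), led by H2-K1 (-2.67) and H2-Q4 (-1.92), near-identical genes between which the read assignment is uncertain. Enzymes of cholesterol synthesis rose in 8 of 22 members and fell in 2 (adjusted p = 0.00723; adjusted p = 0.533 with an estimated correlation), with Msmo1 at 1.74, and adjusted over the list alone 14 rose and 2 fell. Genes of the unfolded protein response fell in 5 of 23 members and rose in 1 (adjusted p = 0.0129; adjusted p = 0.533 with an estimated correlation; 8 and 1 adjusted over the list alone), with Derl1 at -1.77 and Atf6 at 1.22. Glycolysis and hypoxia genes fell in 5 of 15 members, also 5 adjusted over the list alone (adjusted p = 0.0118; adjusted p = 0.545 with an estimated correlation), such as P4ha1 (-2.08). The list had an adjusted p of 0.0604 without AT2 footprint library 2.

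Oncofetal genes rose in 3 of 9 footprint members and fell in 1 (adjusted p = 0.0129, and 0.226 with an estimated correlation), or 5 and 1 adjusted over the list alone. Igf2bp2 (4.15) and Hmga2 (2.89) were higher and Sox9 (-2.11) lower. In library set 2 alone the oncofetal list had an adjusted p of 0.365. The unfolded protein response, NF-kB and oxidative phosphorylation lists also lost their calls there (0.109, 0.260 and 0.118). Replication-dependent histone genes, which share sequence, passed as a list (adjusted p = 0.00723; adjusted p = 0.949 with an estimated correlation) with 1 of 38 members past the gene test and 0 adjusted over the list alone. It had an adjusted p of 0.220 without AT2 footprint library 1. With the library set as a term 27 histone genes rose and 1 fell, and 2 lists that had not passed did so. Translation factors went from 1 of 29 members higher (adjusted p = 0.191) to 13 (adjusted p = 0.0166), and ribosome biogenesis from 1 of 32 higher and 1 lower (adjusted p = 0.191) to 16 and 2 (adjusted p = 0.0166). Nuclear genes of oxidative phosphorylation fell in 10 of 59 members, or 6 adjusted over the list alone (adjusted p = 0.0400; adjusted p = 0.949 with an estimated correlation), such as Ndufb6 (-1.62) and Ndufv3 (-1.44). Its adjusted p was 0.265 and 0.209 without AT2 footprint library 2 or 3, and 0.180 and 0.142 without LUAD library 1 or 2. Scaled on all transcripts it was 0.0571, and with the library set as a term 0.206. Lists that did not pass included RAS-MAPK output, where 4 of 22 members rose and 5 fell (adjusted p = 0.677; 4 and 5 adjusted over the list alone), with Il1rn at 3.95 and Epha2 at -2.91. Markers of other cell types were too few to test as lists. Of 22 defined macrophage and leukocyte markers 2 were measured. Both rose, Cd14 from 4.89 ± 1.40 to 42.7 ± 2.56 CPM and Mrc1 from 1.04 ± 1.35 to 17.5 ± 5.46 CPM. Of 22 defined fibroblast markers 2 were measured and Bgn rose (4.61), and of 4 measured basal markers 2 fell, with Lamb3 at -1.21. Markers entered only with a listed ORF, which favours those translated in LUAD.

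The second comparison measured RNA in the same kinds of organoid. Trp53 RNA stood at 83.5, 85.9 and 165 CPM in the AT2 libraries and at 0, 0, 0 and 2.76 CPM in the LUAD libraries (log2 fold change -7.42 ± 1.45, SE, n = 3 and 4; edgeR adjusted p = 0.00585). DESeq2 gave Trp53 RNA no p-value. It did not pass in library set 2 alone, which holds the LUAD library with Trp53 reads and only the third AT2 RNA library. Nkx2-1 RNA fell from 248 ± 99.1 to 0.0779 ± 0.121 CPM (SD). Sftpb RNA fell from 84.3 ± 64.2 to 0.192 ± 0.157 CPM and Cdkn1a from 488 ± 79.8 to 43.1 ± 17.5 CPM. Hmga2 RNA rose from 0.367 ± 0.636 to 165 ± 7.19 CPM, and Spp1, a secreted matrix protein, from 25.8 ± 20.9 to 1798 ± 156 CPM. Lgals4 had no AT2 read and was at least 268-fold higher, and Ptpn22 and Ltf at least 539- and 367-fold higher, against a floor of 3 counts over the group.

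In all, 2558 of 6942 genes passed in RNA, 1285 higher and 1273 lower in LUAD. Scaling on all transcripts moved the median log2 fold change by 0.171 and gave 1795 higher and 912 lower calls. Lgi3 and Hspb8 had no LUAD RNA read and were at least 7537- and 4069-fold lower, and Sparc, a matrix protein, fell from 830 ± 484 to 0.418 ± 0.400 CPM. The transcription factor Hnf4a rose to 29.5 ± 2.61 CPM from 6 counts over the AT2 libraries, and Igf2bp2 from 0.955 ± 0.713 to 44.1 ± 3.13 CPM. H2-K1 fell by 2.16 on the log2 scale, and B2m (0.01 ± 0.24, adjusted p = 0.969) did not pass. Mki67 rose by 1.26 (adjusted p = 0.0237). Its adjusted p was 0.0891 and 0.0836 without AT2 library 1 or 2, and 0.0504 and 0.0537 without LUAD library 1 or 2. Atf4, a transcription factor of the integrated stress response, rose by 1.04 (adjusted p = 0.0460). Its adjusted p was 0.140 and 0.137 without AT2 library 1 or 2, and 0.107 without LUAD library 3 or 4. Without AT2 RNA library 1 or 2 the test passed 1681 and 1613 genes. Sftpc and Cd74 were not analysed here, since the ORF lists pair no transcript with them, and Ager had too few counts to be tested in either assay.

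Among the lists, 13 passed in RNA, 3 of which also held with an estimated correlation. Gastric and gut endoderm genes rose in 4 of 5 members, also 4 adjusted over the list alone (adjusted p = 3.84e-09, and 0.0395 with an estimated correlation). Anxa10, which had 1 AT2 read, stood at a ratio of 1168 (interval 210 to 46146). As in footprints, only 5 of 25 defined members were paired, through ORF lists that favour LUAD, and 9 of 20 in the oncofetal list. Oncofetal genes rose in 7 of 9 members and fell in 1, the same counts adjusted over the list alone (adjusted p = 3.31e-07; adjusted p = 0.0395 with an estimated correlation). AT2 identity genes fell in 6 of 9 members and rose in 1, also the counts adjusted over the list alone (adjusted p = 1.82e-08; adjusted p = 0.0486 with an estimated correlation), with Lpcat1, a surfactant lipid enzyme, at -3.32 and Muc1 at 0.86. Cell cycle genes rose in 28 of 35 members and in 32 adjusted over the list alone (adjusted p = 3.84e-09; adjusted p = 0.520 with an estimated correlation), including Kif23 (2.95) and Cenpe (2.86). Ribosome biogenesis genes rose in 15 of 33 members and in 18 adjusted over the list alone (adjusted p = 0.000209; adjusted p = 0.667 with an estimated correlation), including Gnl3 (1.84) and Utp20 (1.79). NF-kB and inflammatory genes rose in 12 of 19 members and fell in 2, also adjusted over the list alone (adjusted p = 0.00204; adjusted p = 0.520 with an estimated correlation), with Tnfaip2 at 7.51, the chemokine Cxcl5 at 6.22 and Icam1 at -3.46.

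AT1 genes fell in 9 of 12 RNA members and rose in 2, also adjusted over the list alone (adjusted p = 2.22e-06; adjusted p = 0.357 with an estimated correlation), with Cldn18 at -8.45 and Cav1 at 1.87. MHC class I genes fell in 6 of 10 members and in 7 adjusted over the list alone (adjusted p = 0.000557; adjusted p = 0.243 with an estimated correlation), among them Tapbp (-2.13). Genes of the unfolded protein response fell in 13 of 23 members and in 14 adjusted over the list alone (adjusted p = 0.00380; adjusted p = 0.582 with an estimated correlation), among them Sel1l (-1.82). Targets of p53 fell in 6 of 16 members and rose in 3, or 7 and 3 adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.357 with an estimated correlation), with Sesn2 at -3.56. Transitional alveolar genes fell in 9 of 19 members and rose in 4, also adjusted over the list alone (adjusted p = 0.0134; adjusted p = 0.483 with an estimated correlation), with Itgb6 at -2.84 and Lcn2 at 4.83. Without AT2 RNA library 3 the p53 and transitional lists had adjusted p of 0.171 and 0.280. Mitochondrial ribosomal protein genes rose in 10 of 54 members and in 1 adjusted over the list alone (adjusted p = 0.0449; adjusted p = 0.728 with an estimated correlation), such as Mrps9 (1.24). EMT and mesenchymal genes rose in 4 of 10 members and fell in 2, also adjusted over the list alone (adjusted p = 0.0476; adjusted p = 0.357 with an estimated correlation). With the replicate block these 2 lists had adjusted p of 0.0872 and 0.258. The mitochondrial list had adjusted p of 0.165 and 0.127 without AT2 RNA library 1 or 2, and 0.135 without LUAD RNA library 3 or 4. RNA changes correlated with transcript length across genes (Spearman rho -0.251), and with that trend removed the mitochondrial list had an adjusted p of 0.401, and with the library set as a term 0.0838. The EMT list had 0.165, 0.0951, 0.0727 and 0.0670 without LUAD RNA library 1, 2, 3 or 4, and 0.0518 scaled on all transcripts.

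**Figure D2:**
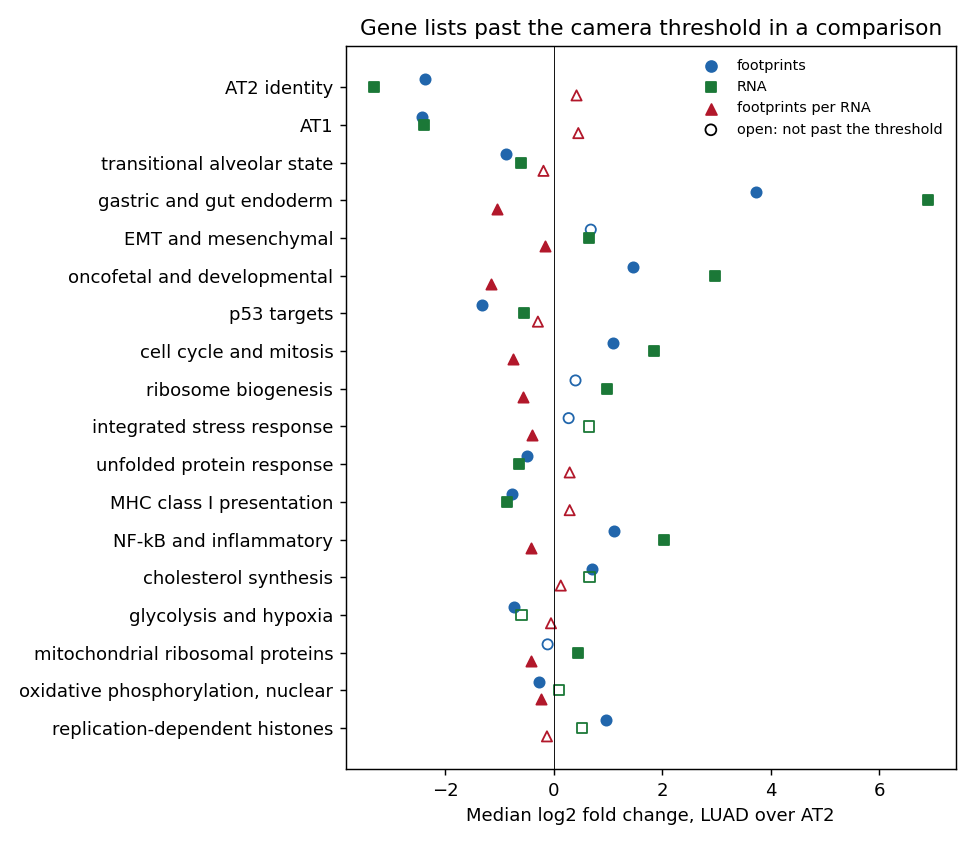
Median log2 fold change (LUAD over AT2) of each gene list past the camera threshold in at least 1 comparison, for footprints (circles), RNA (squares) and footprints per RNA (triangles), with open marks where the list did not pass. The gastric and gut endoderm list has the highest median in footprints (3.72) and RNA (6.89), over 5 measured of 25 defined members.

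Footprint changes were next set beside RNA changes over 6715 genes tested in both assays. Log2 fold changes correlated across genes with a Pearson r of 0.752 and a Spearman rho of 0.715, where genes are not independent replicates, and the slope of footprints on RNA was 0.600. Of 2520 genes past the RNA test, 2335 (92.7%) had the same sign in footprints. Both tests were passed by 1033 genes, against 542 for independent lists. Directions were opposite in 4 of them, Ppp3r1, Cactin, Arglu1 and Set, which were named after their values were seen. Cactin fell in footprints (-1.04) and rose in RNA (0.78). Without AT2 footprint library 1 r was 0.570.

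**Figure D3:**
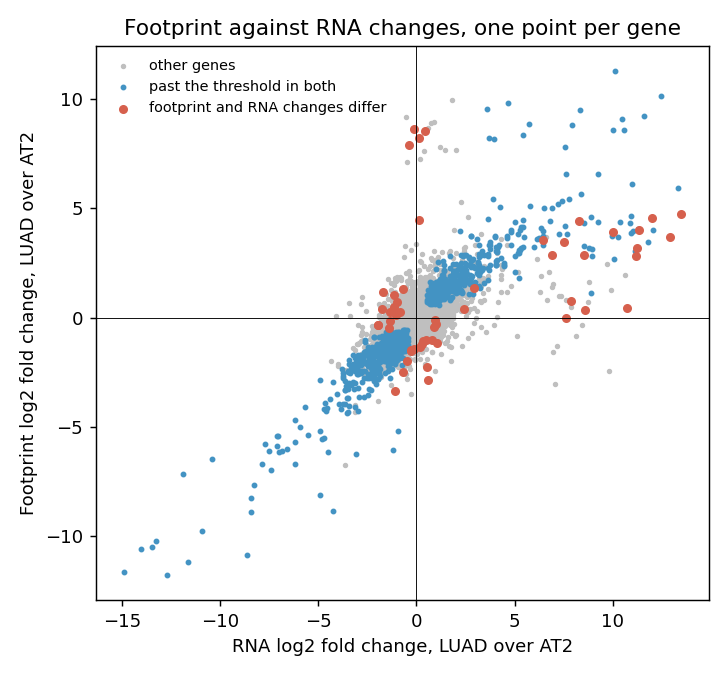
Footprint log2 fold change (LUAD over AT2) against RNA log2 fold change, 1 point per gene. Blue points passed both tests and red points passed the test of the difference between the assays, and over all 6715 genes Pearson's r is 0.752.

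The third comparison asked where footprints per RNA, often called translational efficiency, differed, as the interaction of tissue and assay over all 14 libraries. In all, 53 of 7086 genes passed, 18 higher and 35 lower in LUAD, and in 19 of them at least 1 group held under 20 counts. Scaling on all transcripts moved the median change by 0.287 and gave 26 higher and 13 lower calls. With the library set as a term, which was drawn from these same libraries, 507 genes passed, all 53 among them, with 249 higher and 258 lower. Set 1 holds 1 AT2 footprint library but 2 AT2 RNA libraries, beside 2 LUAD libraries of each assay. A difference between the sets can therefore enter this interaction. Hmga2 fell by 5.57 ± 0.75 (log2 footprints per RNA, SE; edgeR adjusted p = 0.00857), with 117 footprint and 11 RNA counts in AT2 against 4871 and 20457 in LUAD. Tnfaip2 fell by 3.96 and Kif23, a motor protein of cell division, by 1.53 (adjusted p = 0.0361 and 0.0447), and the initiation factor Eif4b rose by 1.12 (adjusted p = 0.0257). On the transcripts paired through the ORF lists, Arhgap11a had 493 footprint and 0 RNA counts in AT2 against 3899 and 1209 in LUAD. Ltf had 41 and 0 against 3161 and 5726. Cth, an enzyme of cysteine synthesis, had 18 and 0 against 739 and 1737. Get4 had 0 footprint counts beside 1411 RNA counts in AT2 and 224 beside 8546 in LUAD. Cers6 rose by 2.21 and Zfp809 by 2.24 (adjusted p = 0.0244 and 0.0387). Without AT2 footprint library 1 there were 423 calls, without AT2 RNA library 3 there were 241, and without each other library from 13 to 63. Without AT2 RNA library 1 the adjusted p was 0.114 for Tnfaip2, 0.0992 for Kif23, 0.0654 for Eif4b and Zfp809, 0.0602 for Arhgap11a and Ltf and 0.0572 for Cers6.

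Of the lists, 9 passed as lower in footprints per RNA, and 1 of them, the oncofetal list, held with an estimated correlation (adjusted p = 6.85e-07; adjusted p = 0.00457 with an estimated correlation). In it 1 of 9 members, Hmga2, fell by the test over all genes and 4 did adjusted over the list alone. Cell cycle (median -0.75, adjusted p = 0.000192; adjusted p = 0.831 with an estimated correlation) and ribosome biogenesis genes (median -0.57, adjusted p = 0.00136; adjusted p = 0.831 with an estimated correlation) had 1 of 35 and 0 of 33 members past the gene test, and 2 and 0 adjusted over the list alone. EMT and mesenchymal genes passed too (adjusted p = 0.00945; adjusted p = 0.262 with an estimated correlation), with 1 of 10 members lower and 2 adjusted over the list alone. The other passing lists were mitochondrial ribosomal proteins (adjusted p = 0.00364), NF-kB and inflammatory genes (0.0394), gastric and gut endoderm (0.0443), the integrated stress response (0.0444) and oxidative phosphorylation (0.0444), with adjusted p of 0.831, 0.831, 0.262, 0.831 and 0.831 with an estimated correlation. With the replicate block the gastric list had an adjusted p of 0.0766, and scaled on all transcripts the oxidative phosphorylation list had 0.118. Their members past the gene test numbered 0 of 55, 1 of 19, 0 of 5, 1 of 24 and 0 of 63, and adjusted over the list alone 0, 3, 1, 1 and 0, of which 1 NF-kB gene was higher. The change in footprints per RNA correlated with transcript length across genes (Spearman rho 0.369), and with a length trend removed 4 lists passed, namely oncofetal, cell cycle, ribosome biogenesis and EMT. Single left-out libraries ended every one of these list calls but those of the oncofetal, cell cycle and EMT lists, with 3 calls without AT2 footprint library 2 and 14 without library 1. There were 5 without AT2 footprint library 3, AT2 RNA library 1 or 2 or LUAD RNA library 3. With at least 20 counts in every library the EMT list had an adjusted p of 0.249, and the oncofetal and gastric lists kept fewer than 5 members and had no test. With the library set as a term 5 of the 9 calls ended, and those of the oncofetal, cell cycle, ribosome biogenesis and EMT lists did not. All 9 lists but the integrated stress response and oxidative phosphorylation had passed as higher in RNA. The AT2 identity, AT1, unfolded protein response and MHC class I lists, lower in RNA, had positive medians here (0.42, 0.45, 0.29 and 0.29). Those of the transitional and p53 lists were -0.19 and -0.29, and none of these 6 lists passed. Footprint changes were smaller than RNA changes across genes (slope 0.600). Whether the list calls go beyond that was not tested.

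The last comparison concerned the ORFs listed as translated, in 2 AT2 and 3 LUAD libraries described as independent cultures or tumour-derived organoids. The lists held 2597 and 4426 ORFs in AT2 and 13380, 8122 and 5372 in LUAD, means of 3512 ± 1293 and 8958 ± 4069 (SD), a ratio of 2.55 (exact permutation p = 0.2, two-sided), or 4.08 at an ORF p under 0.005 (p = 0.2). A comparison of 2 with 3 libraries cannot give a p below 0.1. The number of footprint positions implied by the lists ran from 1.42 to 11.82 M a library, and the list with the most positions was the longest. AT2 list 1 and LUAD list 2, with 2.70 and 2.73 M positions, held 2597 and 8122 ORFs, and AT2 list 2, with the fewest positions, held 4426. ORFs other than annotated coding sequences made up 43.7% (exact binomial 95% interval 41.8 to 45.6) and 29.6% (28.3 to 31.0) in AT2 and 34.0% (33.2 to 34.9), 30.2% (29.2 to 31.2) and 33.2% (31.97 to 34.5) in LUAD, a difference of -4.18 points (exact permutation p = 0.6). With equal numbers of the best-supported ORFs the difference was -16.4 points (exact permutation p = 0.1, the smallest possible). That number, 2597, was the full length of AT2 list 1, so only the longer lists lost their least-supported ORFs. Other ORFs had lower median positions than annotated coding sequences in every list, such as 82 against 199 in LUAD list 1. The cut thus favours annotated ORFs in longer lists whatever the tissue, and cannot decide on a tissue difference. At an ORF p under 0.005 the difference was -9.76 points (exact permutation p = 0.3). It was -9.54 without noncanonical ORFs that share a coding stretch (exact permutation p = 0.3) and 2.85 without AT2 list 1. ORFs on noncoding transcripts took 20.2 ± 1.99% in AT2 and 22.5 ± 0.71% in LUAD and ORFs inside a coding sequence in another frame 7.40 ± 4.78% and 2.96 ± 1.22%. ORFs overlapping the end of a coding sequence took 2.73 ± 0.44% and 2.05 ± 0.22%, and each of these 3 classes had an exact permutation p of 0.1, the smallest possible. Upstream ORFs made up 0.44 ± 0.40% and 0.46 ± 0.07% (exact permutation p = 1).

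**Figure D4:**
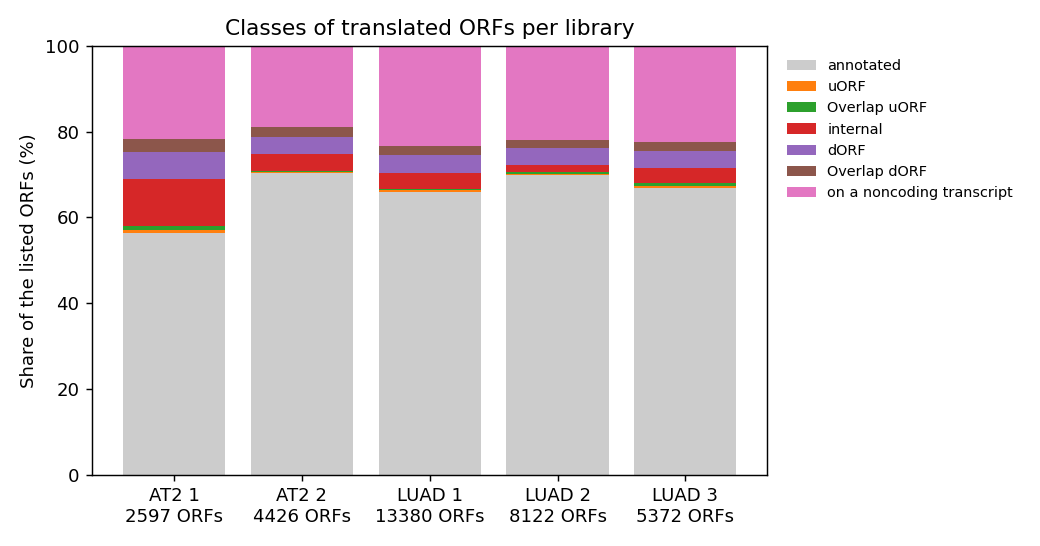
Share of the listed ORFs (%) in each class for the 2 AT2 and 3 LUAD libraries, with the number of ORFs under each bar. Annotated coding sequences are grey and make up from 56.3% to 70.4% of a list.

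In all 3 LUAD lists and neither AT2 list there were 695 ORFs, of which 527 were annotated coding sequences and 168 were of other classes, while 106 ORFs were in both AT2 lists and no LUAD list. The same count for the other choices of 3 of the 5 libraries ran from 13 to 739, so 2 of the 10 choices gave as many. Without AT2 list 1 or 2 the LUAD count was 761 and 1193 and the AT2 count, then of a single list, 1239 and 1388. Without LUAD list 1, 2 or 3 the LUAD counts were 1155, 1738 and 2898 and the AT2 counts 173, 140 and 119. Among the 168, those with the most footprint positions lay on transcripts of Ctnnb1, the gene of beta-catenin (mm10, chromosome 9, 120950703 to 120959517, 675 amino acids, 2458 ± 1465 positions, SD, n = 3), Nedd4 (chromosome 9, 72726509 to 72747228, 522 amino acids), Ywhae (chromosome 11, 75733028 to 75757027, 193 amino acids), Ankrd1 (chromosome 19, 36115299 to 36119781, 274 amino acids) and Rack1, a ribosomal scaffold protein (chromosome 11, 48802202 to 48806045, 247 amino acids). A second ORF of Ctnnb1 and ORFs of Flna, Hsp90ab1, Myof and Smc4 completed the 10 with the highest support. These positions were counted over all 3 reading frames. Of the positions of these 10 ORFs, from 36.8% to 51.7% were in frame in a LUAD list. Annotated coding sequences had from 44.1% to 47.8% in frame over the 5 lists. The in-frame excess was thus modest even there, which limits all ORF calls and class shares. All 10 shared a stretch of at least 10 amino acids with an annotated ORF of their own gene, as did 164 of the 168. Of the 4 without such a stretch, 3 (Cdk17, Ahcyl1 and Rnf128) belong to genes with no annotated ORF in any list, so sharing was not testable for them. The last was a 60 amino acid ORF overlapping the start of Fem1b (chromosome 9, 62811229 to 62811411) with 32.3 ± 17.2 positions.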

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

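The test with a gene length trend removed and the tests of footprints without RNA were chosen after the results were seen, and those of library depth and of the most abundant genes before.

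Chance puts about 1 in 20 groups of 4 past the limit for a sample far from the others, and 4 of 32 groups passed it. That rate does not hold for 2 of the 4, Nkx2-1 footprints and Trp53 RNA, where 1 value beside 3 zeros always passes. The first LUAD footprint library was the shallowest, at 4.80 M estimated counts against 13.34 to 14.25 M in the others. That library also held the Nkx2-1 footprints of the LUAD group, at 0.347 CPM against 0. The fourth LUAD RNA library held the Trp53 RNA reads of its group, at 2.76 CPM against 0. Igf2bp2 RNA stood at 48.8 CPM in the third LUAD RNA library against 42.1 to 42.9 CPM in the others. Transcripts that the ORF lists pair with no gene, which no comparison used, included 872 of 13332 tested past the edgeR test in footprints (458 higher and 414 lower in LUAD) and 1065 of 15551 in RNA (683 higher and 382 lower).

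The libraries of both tissues fell into the same 2 sets, which the labels do not name. Set 1 held the first AT2 and the first 2 LUAD footprint libraries and the first 2 RNA libraries of each tissue, and set 2 the rest. AT2 and LUAD deviations from their group means correlated from 0.32 to 0.50 within a set and from -0.50 to -0.24 across sets in footprints, and from 0.23 to 0.33 and -0.36 to -0.22 in RNA. The gap between the mean correlations within and across sets, 0.761 in footprints and 0.558 in RNA, was 0.719 and 0.485 with all libraries thinned to the depth of the smallest, 0.648 and 0.397 with a length trend removed, and 0.728 and 0.541 without the 10 most abundant genes of each library, so none of these accounts for the sets alone. A shared preparation or sequencing batch stays open and untested, since no label gives one, and no biological explanation was tested.

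Genes with few or no AT2 RNA counts still had AT2 footprints. Counts cover only transcripts paired through the ORF lists. AT2 RNA on unpaired transcripts of these genes was not counted, and this explanation was not tested. Of 33 genes with at most 3 AT2 RNA counts in all and at least 100 in every LUAD RNA library, 29 had AT2 footprints. The median over the 33 was 5.89% of the LUAD level (quartiles 4.37 to 13.6%), and the 33 include 9 of the 35 genes lower in footprints per RNA. Counting error at the depth of AT2 RNA does not account for 18 of the 29, which had fewer RNA counts than an exact binomial test corrected over 6119 genes allows at the share their footprints kept, and for the other 11 it stays open. LUAD footprint reads carried into the AT2 libraries at one share would give these genes one fold. Of the 28 with AT2 footprints and a footprint test, 3 (Arhgap11a, Fastkd3 and Unc5b) lay outside the 99% range around the median fold. This argues against such carry-over for them. The 4 of 33 without AT2 footprints (Lgals4, AA467197, Hgfac and Cdh13) would have had 23.7 in all at the median share. That argues against one share as high as the median. Folds of the other 25 genes lie within the range, which is centred on the median fold of these same genes and so cannot decide. For them carry-over at a lower share and translation of rare transcripts cannot be told apart.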

How the results depend on the processing

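The alternatives with library sets, scaling on all transcripts, a length trend, Mettl26 left out, 20 counts in every library and ORFs sharing a stretch left out were chosen after the data were seen. Of the genes named by rule that passed, all 64 in footprints, 69 in RNA and 20 in footprints per RNA kept their direction in every setting that gave them a value. The rule takes genes with the largest changes in these same libraries, so a kept direction was nearly fixed in advance. Calls were kept in every such setting by 56, 61 and 1. With at least 20 counts in every library 4 of the 20 had a value, and the oncofetal and gastric lists had none. With protein-coding transcripts alone the gastric list had none in footprints. Calls in footprints fell to 933 with the replicate block, where numbers do not pair the libraries (correlations from -0.35 to 0.40), and rose to 2882 with the library set as a term, 3562 in set 1 alone and 2863 in set 2 alone. RNA calls rose to 4037 in set 1 alone. Calls in footprints per RNA rose to 375 with the DESeq2 Wald test, 91 with length-scaled counts, 90 with the replicate block, 507 with the set as a term and 859 with that term and no first AT2 footprint library. The block joins footprint and RNA libraries of one number, which correlated from -0.19 to 0.24 in AT2 and from 0.41 to 0.50 in LUAD. The AT2 numbers thus do not pair the assays. With an estimated correlation 0, 3 and 1 lists passed in footprints, RNA and footprints per RNA. In the last, 5 lists passed with the set as a term (histones, as higher, among them), 4 with the length trend removed and 4 with at least 20 counts in every library (cell cycle, ribosome biogenesis, mitochondrial ribosomal proteins and oxidative phosphorylation). ORFs recurrent in LUAD numbered 189 at p under 0.005 and 258 with equal list lengths. The cause of these shifts was not tested.

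Leaving out single libraries gave 841 to 1888 calls in footprints, 1613 to 3362 in RNA and 13 to 423 in footprints per RNA, 11 to 15, 11 to 15 and 3 to 14 lists, a correlation of fold changes from 0.570 to 0.791, an ORF number ratio from 1.92 to 3.45, a difference in noncanonical share from -11.2 to 2.85 points and 761 to 2898 recurrent ORFs. The share reversed, to 2.85, without the first AT2 list. Atf4 footprints, which did not pass, had a log2 fold change of -0.64 in set 1 alone, whose only AT2 footprint library is the first. In set 2 alone Atf4 footprints passed as higher. B2m RNA, which did not pass, changed sign to -0.0059 with at least 50 counts, -0.22 with the length trend removed and -0.26 in set 2 alone. Without single libraries B2m RNA ran from -0.15 to 0.16, with -0.05 without AT2 RNA library 3 and -0.07 without LUAD RNA library 1. In set 1 alone B2m RNA passed, as higher. The oxidative phosphorylation list turned higher in footprints per RNA with the length trend removed (adjusted p = 0.909). With the replicate block in RNA, 2640 genes passed, and beside the 3 list calls given with it the block ended no other list call.

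Real groups gave 1452, 2558 and 53 calls in footprints, RNA and footprints per RNA, and the highest of the other 34 of 35 splits 44, 7 and 1. In each, 1 of 35 gave as many, the smallest share this test can give. The test treats libraries as freely exchangeable, which the 2 library sets go against, and libraries of one kind may be technical repeats. Chance is therefore not excluded. Splits that exchange libraries only within the 2 library sets number 18 in footprints and 18 in RNA, too few for a share under 0.05. They gave 1452 and 2558 calls for the real groups and 0 for the highest other. Footprints per RNA had no such count. For list counts chance cannot be excluded either, since 8, 7 and 4 of the 35 splits gave as many as the 14, 13 and 9 seen, with highest others of 16, 14 and 11. Of the other splits that gave as many lists, 12 of 16 over the 3 comparisons had 2 or 0 AT2 libraries among their 3 and so kept part of the tissue difference, against 16 of 34 among all other splits of a comparison. These split predictions were written after the counts were seen. The 2-fold changes of the simulated data, placed in well-covered genes alone, were recovered in 7%, 21% and 4%. AT2 footprint libraries held 3.03 to 3.83 M counts, and whether that depth limited recovery was not tested.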

Other observations

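Both tests on ORF stretches, and those with a length trend removed, scaling on all transcripts or the library set as a term, were chosen after the results were seen.

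Other lists showed single genes that moved while the list did not pass. Of 21 fatty acid and surfactant lipid genes, 3 rose and 6 fell in RNA, also adjusted over the list alone (adjusted p = 0.552), with Hilpda, a lipid droplet protein, at 4.30 and the desaturase Scd1 at -3.10, and in footprints 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.789). NRF2 antioxidant genes rose in 5 and fell in 4 of 18 RNA members, also adjusted over the list alone (adjusted p = 0.329), and rose in 5 and fell in 2 of 17 in footprints (adjusted p = 0.470), with Gsta4 at 2.73 and Gsr at 2.08 in RNA and Pgd at -1.17. Integrated stress response genes rose in 10 and fell in 2 of 24 RNA members, or 11 and 2 adjusted over the list alone (adjusted p = 0.0798), among them Shmt2 (1.72), and 1 rose and 1 fell in footprints (adjusted p = 0.789). Translation factors rose in 5 and fell in 3 of 29 RNA members, also adjusted over the list alone (adjusted p = 0.329), with Eif4ebp1 at 1.40 and Eif4b at -0.82, and rose in 1 of 29 in footprints, Eif5 (adjusted p = 0.191). Interferon genes fell in 3 and rose in 1 of 9 footprint members, also adjusted over the list alone (adjusted p = 0.583), with Ifih1 at -2.49, and fell in 2 of 9 in RNA (adjusted p = 0.505). Glycolysis and hypoxia RNA fell in 8 of 15 members and 9 adjusted over the list alone (adjusted p = 0.0555), and cholesterol RNA rose in 9 of 22 and 10 adjusted over the list alone (adjusted p = 0.0587). With the length trend removed the glycolysis list passed in RNA (adjusted p = 0.0281), as did oxidative phosphorylation (adjusted p = 0.0125), which fell in 5 of 63 RNA members and 3 adjusted over the list alone (adjusted p = 0.716), and with the library set as a term the cholesterol list did (adjusted p = 0.0477). Scaled on all transcripts the cholesterol (adjusted p = 0.0339), proteasome (0.0290) and cytosolic ribosomal protein lists (0.0336) passed as higher in RNA.

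Cytosolic ribosomal protein genes rose in 8 and fell in 1 of 28 RNA members, also adjusted over the list alone (adjusted p = 0.0837), and rose in 1 and fell in 1 of 27 in footprints (adjusted p = 0.908). Proteasome genes rose in 7 of 30 RNA members and 2 adjusted over the list alone (adjusted p = 0.0725), and in 1 and 0 of 30 in footprints (adjusted p = 0.668). Of 5 mitochondrially encoded genes 1 fell in RNA (adjusted p = 0.346) and 0 in footprints (adjusted p = 0.752). Histones rose in 5 and fell in 3 of 28 RNA members (adjusted p = 0.506). Of the remaining markers, the 1 club and the 1 neuroendocrine gene measured did not pass over all genes in either assay. RNA of both measured macrophage markers, Cd14 (3.73) and Mrc1 (5.19), rose, as did that of Bgn, 1 of 2 measured fibroblast markers. Mettl26 took 36.0% of all counts in the first AT2 footprint library, 2.90 and 1.36% in the others and at most 0.936% in LUAD, beside at most 0.0129% in RNA.

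ORFs on noncoding transcripts numbered 5179 over all lists, and 5046 of them lay in protein-coding genes. Of the 4748 whose gene has an annotated ORF listed, 95.9% shared a stretch of 10 amino acids with it, and 0.21% did with the ORFs of another gene, so chance matches do not account for the sharing. Footprints on coding sequence that the noncoding transcript shares with its gene may therefore be counted for this class.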
